A study of Mus musculus with 12 samples.

How the data were processed

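Gene expression was measured on Illumina BeadChip arrays in 12 mouse SHH medulloblastoma samples. Per the labels, 4 were primary tumours and 4 metastatic tumours of Math1-cre;A1G;Ptch1+/- mice, here called A1G primary and A1G metastatic, and 4 were tumours of Ptch1+/- mice, here called Ptch1het. The labels do not expand A1G, do not give the site of the metastases, and word the genotype of metastatic replicates 2 and 3 differently from that of replicates 1 and 4. They also do not say that replicates are separate animals, so every p-value measures the spread between these samples. Per the labels' protocols, tumours were homogenized in Trizol, total RNA was treated with DNase I and checked on a Bioanalyser, and biotinylated cRNA was prepared for the arrays.

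The deposited values are probe intensity on a linear scale for 45281 probes. From the values, the authors had already normalized between arrays, since the medians of all 12 arrays lay at 187 (linear scale). The method is not given in the sources used here, and the background had not been subtracted. A second deposited table of signals and detection p-values names its 24 per-array columns by chip and position only. These match no sample label, so these columns were not used, and only the probe annotation was read from that table. Its header shows 2 chips of 6 arrays; which sample lay on which chip is not given in the sources used here, so chip is a possible confounder that could not be tested.

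The planned background correction by detection p (neqc) and filter on detection p were therefore replaced by the fallback fixed in the design and by a signal filter chosen after the files were seen. Intensities were background corrected by normexp with an offset of 50, quantile normalized and log2 transformed in limma 3.58.1 under R 4.3.3. A probe was kept when its signal was above the median of its array on at least 4 of 12 arrays, which left 24443 probes (54.0%). Gene symbols came from the deposited annotation and were matched to current names: 27740 probes carried a current symbol, 8037 were updated through a synonym and 9504 kept the symbol of the annotation. Each gene was represented by its probe with the highest mean log2 signal over all arrays, giving 16724 genes, 11491 with 1 probe and 5233 with several.

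One linear model with the 3 groups was fitted to all 12 arrays with limma (lmFit and eBayes; 9 residual and 3.67 prior degrees of freedom). The comparisons were A1G metastatic minus A1G primary, A1G primary minus Ptch1het, and, as a secondary comparison in which genotype and tumour site both differ, A1G metastatic minus Ptch1het. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. In addition, 30 gene lists of pathways and cell types with 538 entries, of which 429 were tested, were compared by limma camera at a preset correlation of 0.01, adjusted over the 30 lists of each comparison. The groups, comparisons, tests, lists, threshold and the choice of genes to name were fixed before the data were examined.

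Genes were named by that rule. Among genes that passed with every array of one group above every array of the other, these were the 10 with the largest rise and the 10 with the largest fall. Where fewer than 10 genes passed, all of them were named, with the 5 highest and 5 lowest log2 differences among the 50 smallest p-values. Up to 4 members with the smallest p of each described list, and Atoh1, Ptch1, Gli1, Gli2 and Mycn, were added. Some genes that met the rule are not reported here. Values are means of log2 signal with the standard deviation (SD) over n = 4 arrays; differences carry the standard error (SE) of the model. Where a gene was at or below the array median in every array of a group, its level there is not resolved from background. Its fold is then given as "at least", computed by setting the dim group to the array median, 7.05 on the log2 scale. Where only some arrays of a group were at or below it and the group mean was too, means or the log2 difference are given without a fold.

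The intensity of the dimmest probes and 4 arrays per group limit precision. The fit was tested on simulated data with 200 of 16724 genes changed: for the metastatic minus primary comparison it recovered 68.0% of 2-fold and 93.0% of 4-fold changes with 6 false calls. For A1G primary minus Ptch1het these were 68.0%, 96.0% and 6, and for metastatic minus Ptch1het 73.0%, 92.0% and 12. In each, the shifted list was called and 0 of 29 unchanged lists were. Each simulation used the same gene means and spreads, so differences between the comparisons come from the random draws. Recovery was not tested for other numbers of changed genes. The simulated genes varied independently, without correlation within lists or pairing of arrays. The estimated correlation of the real lists reached 0.84, so this check does not give the rate of false list calls in the real data. Replicate numbers were checked as possible pairs: after removal of group means, A1G primary and metastatic arrays of the same number correlated at 0.45, 0.17, 0.21 and 0.27, all above 0.1, so results with a replicate block are given where they change a call.

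Alternatives planned beforehand were no background correction, the deposited values as they are, median centring, no filter, the mean of a gene's probes, every probe on its own, only the 8 arrays compared, a replicate block, array weights, trended and robust moderation, a fold of at least 1.5, an adjusted p under 0.01, each array left out in turn, an estimated correlation per list, and the rotation test fry. Added after the data were seen were a filter on all 12 arrays, the block with only 8 arrays, metastatic replicates split by label wording, the Y-linked gene Eif2s3y as a covariate, and leaving out A1G primary and Ptch1het replicates 4 together.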

Results

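Mouse medulloblastomas of the SHH subgroup were compared between primary and metastatic tumours of Math1-cre;A1G;Ptch1+/- mice and tumours of Ptch1+/- mice, with 4 arrays each. The eGFP probe read 12.28 ± 0.61 in A1G primary and 12.15 ± 0.92 in A1G metastatic tumours against 7.58 ± 0.40 in Ptch1het tumours (log2, SD, n = 4). Atoh1, Gli1 and Mycn, which mark granule neuron progenitors and SHH signalling, had no probe above the array median on any of the 12 arrays and were not tested. The first principal component (34.8% of the variance) placed the metastatic tumours between 30.44 and 64.40 and the other 8 arrays between -32.59 and -15.31.

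In metastatic against primary A1G tumours, several of the largest rises were in genes of peripheral neurons. Sncg, a synuclein of peripheral neurons (chromosome 14), rose from 7.45 ± 0.31 to 13.54 ± 0.47 (SD, n = 4), a log2 difference of 6.09 (SE 0.51), or 68.3-fold (adjusted p = 1.21e-05). Prph, the intermediate filament peripherin (chromosome 15), rose from 6.81 ± 0.38 to 12.35 ± 0.61 (adjusted p = 9.86e-08). Scn11a, a sodium channel of pain-sensing neurons, rose from 6.65 ± 1.19, with 3 of 4 primary arrays below the array median, to 11.81 ± 0.82 (adjusted p = 0.000189). Avil, an actin regulator of sensory neurons, rose at least 19.8-fold (means 6.20 and 11.36, adjusted p = 1.01e-06).

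Matrix, muscle and other genes completed the largest rises. Ogn, a small matrix proteoglycan, rose from 6.83 ± 0.51 to 11.51 ± 0.30 (log2 difference 4.68, SE 0.31, adjusted p = 1.61e-06), although its other probe differed by only 1.00. Mfap5, a microfibril protein, rose at least 14.7-fold (means 6.27 and 10.92, adjusted p = 2.52e-07), Tmem45b at least 14.4-fold (6.11 and 10.89, adjusted p = 7.98e-06) and LOC100045304 at least 15.9-fold (6.38 and 11.04, adjusted p = 1.63e-07). Atp2a1, the calcium pump of fast skeletal muscle, rose by a log2 difference of 4.55 but varied widely among metastatic tumours (mean 11.56, SD 2.67, adjusted p = 0.0106).

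The largest falls included Gpr17, Cspg5 and Nkx2-2. Gpr17, a receptor of oligodendrocyte precursors (chromosome 18), fell by 3.13 on the log2 scale (SE 0.59, 10.54 ± 0.15 to 7.41 ± 1.14, adjusted p = 0.00686). Cspg5, a brain chondroitin sulfate proteoglycan, fell by 2.51 (SE 0.39, 10.44 ± 0.55 to 7.93 ± 0.87, adjusted p = 0.00165), and Nkx2-2, a transcription factor of oligodendrocyte specification, by 2.07 (SE 0.41, 8.59 ± 0.22 to 6.53 ± 0.94, adjusted p = 0.00849). Vxn fell by 2.68 (adjusted p = 0.00749), the secreted synaptic protein gene C1ql2 by 2.30 (adjusted p = 0.0103) and the matrix protein gene Matn4 by 1.94 (adjusted p = 0.00676). Further falls passed but were lost when single libraries were left out. Gria1 fell by 2.45 (adjusted p = 0.0293, and up to 0.0966 without primary 1, 2 or 4 or metastatic 1, 2 or 3, and 0.131 with the mean of its probes) and Scrg1 by 2.07 (0.0219, and up to 0.0655 without primary 1, 2 or 4 or metastatic 1 or 3). Cd70 fell at least 2.48-fold (means 8.36 and 6.33, adjusted p = 0.0241, and up to 0.0843 without primary 1 or 2 or metastatic 1 or 2). Ptprz1 fell by 1.88 (0.0349, and up to 0.0963 without any one primary or without metastatic 1, 2 or 3), and its adjusted p was 0.0638 with a replicate block.

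**Figure D1:**
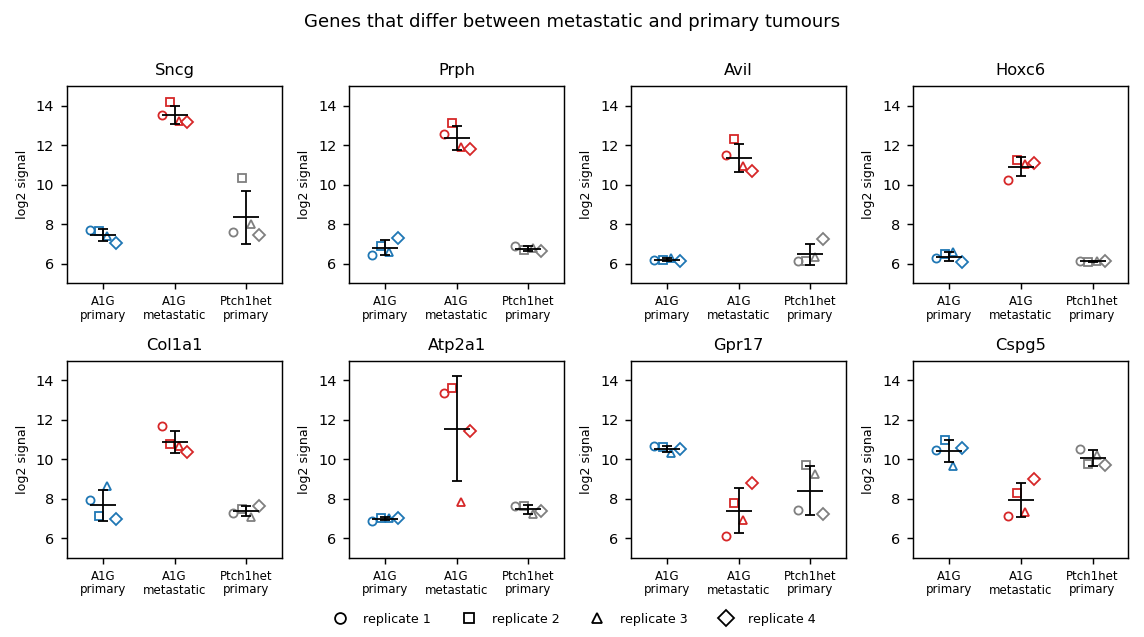
Log2 signal of 8 genes in each array of the 3 groups, with symbols for the replicate number and bars for mean ± SD (n = 4). Sncg averaged 13.54 in metastatic and 7.45 in A1G primary tumours, and Gpr17 averaged 7.41 and 10.54.

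Schwann cell, spinal cord, matrix and meningeal genes rose in metastatic tumours under both the preset and the estimated correlation. Of 8 tested Schwann cell markers 6 rose (6 adjusted over the list alone, median log2 2.77, adjusted p = 8.12e-18, and 0.00247 with an estimated correlation). Pmp22, a peripheral myelin protein, rose 12.2-fold (12.99 ± 0.08 against 9.39 ± 0.28, adjusted p = 5.31e-07), Prx at least 5.45-fold (means 6.44 and 9.49, adjusted p = 3.04e-08) and Pmp2 at least 9.32-fold (6.63 and 10.27, adjusted p = 4.05e-06). Of 16 spinal cord and hindbrain genes 12 rose (13 over the list alone, median 2.45, adjusted p = 2.8e-22, and 0.00247 with an estimated correlation). The Hox genes, which pattern the body axis, included Hoxc6, at least 14.5-fold (means 6.36 and 10.91, adjusted p = 4.54e-08), Hoxb7, at least 7.94-fold (6.19 and 10.04, adjusted p = 2.4e-07), and Hoxa5, at least 5.22-fold (6.0 and 9.43, adjusted p = 1.51e-06).

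Extracellular matrix genes rose in 21 of 26 tested members (23 over the list alone, median 1.93, adjusted p = 7.67e-30, and 0.00247 with an estimated correlation). Bgn, which encodes biglycan, rose 7.85-fold (11.32 ± 0.44 to 14.29 ± 0.25, adjusted p = 0.000114) and the fibrillar collagen genes Col1a1 and Col1a2 rose 9.20-fold (adjusted p = 0.000131) and 5.60-fold (adjusted p = 2.33e-05). Of 18 meningeal fibroblast markers 10 rose (15 over the list alone, with 1 lower, median 1.86, adjusted p = 2.17e-14, and 0.00247 with an estimated correlation). Among them Dcn, which encodes decorin, rose 8.84-fold (adjusted p = 0.00157). The meningeal list shares Dcn, Lum, Col1a1 and Col1a2 with the matrix list, so the rises of these lists are not independent.

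Skeletal muscle markers rose in 5 of 7 members (6 over the list alone, median 3.30, adjusted p = 3.84e-07, but 0.196 with an estimated correlation). Tnnt3, a fast muscle troponin, rose at least 6.30-fold (means 6.40 and 9.70, adjusted p = 0.014), and Myl1 rose by a log2 difference of 4.08 (adjusted p = 0.023, and up to 0.0712 without primary 1, 2 or 3 or metastatic 1, 2 or 4). The mean of the list was 12.06, 12.58, 7.62 and 10.52 in metastatic replicates 1 to 4 and between 6.90 and 8.53 in A1G primary tumours.

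Genes of mesenchymal transition and of signalling through BMP and TGF-beta rose as lists at the preset correlation only. Of 22 epithelial-mesenchymal transition genes 6 rose (12 over the list alone, median 0.55, adjusted p = 1.29e-09, but 0.0606 with an estimated correlation). Risen members were the collagen cross-linking enzyme Lox (9.50-fold, adjusted p = 0.000171), S100a6 (6.47-fold, adjusted p = 0.000306), the metalloproteinase Mmp2 (2.21-fold, adjusted p = 0.00326) and the repressor Snai2 (at least 1.65-fold, means 6.61 and 7.77, adjusted p = 0.00685). Of 13 BMP and TGF-beta genes 4 rose (6 over the list alone, median 0.58, and 0.29 without metastatic 4, adjusted p = 0.00143, but 0.104 with an estimated correlation). The TGF-beta induced Tgfbi rose 5.39-fold (adjusted p = 0.00423) and the ligand Bmp4 3.74-fold (adjusted p = 0.0116). The transition list shares Fn1, Tnc and Postn with the extracellular matrix list. Which cells carried these rises was not tested.

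Immune and vascular lists also rose at the preset correlation only. Microglia and macrophage markers rose in 2 of 20 members (8 over the list alone, median 0.60, adjusted p = 1.76e-07, but 0.249 with an estimated correlation). The macrophage mannose receptor Mrc1 was among these (2.28-fold, adjusted p = 0.0131). Of 9 lymphocyte markers 5 rose (5 over the list alone, median 0.73, adjusted p = 6.81e-05, but 0.0742 with an estimated correlation). Nkg7 rose at least 1.89-fold (means 6.71 and 7.96, adjusted p = 0.00134) and Cd3g at least 1.5-fold (6.54 and 7.64, adjusted p = 0.00767). Interferon and MHC genes rose in 3 of 25 members (12 over the list alone, median 0.76, and 1.18 without primary 2, adjusted p = 3.92e-08, but 0.249 with an estimated correlation). Cd74, the invariant chain that associates with MHC class II, rose by 1.84 on the log2 scale (adjusted p = 0.0309, and up to 0.105 without primary 1 or 4 or metastatic 2 or 4). Mural cell markers held 3 rises and 1 fall among 10 (5 and 1 over the list alone, median 0.94, adjusted p = 0.0078, but 0.37 with an estimated correlation). The pericyte receptor Pdgfrb rose 2.92-fold (adjusted p = 0.00139). Endothelial markers rose in 2 of 16 (2 over the list alone, median 0.48, adjusted p = 0.0227, but 0.622 with an estimated correlation). This list did not pass without primary 2 (0.0746), metastatic 2 (0.103) or metastatic 4 (0.248), and its median was 0.31 without metastatic 2 and 0.74 without metastatic 3.

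Stress-related and neuronal lists also passed at the preset correlation only. Of 15 immediate early genes 3 rose (3 over the list alone, median 0.17, adjusted p = 0.0278, but 0.249 with an estimated correlation). Klf4, a stress-induced transcription factor, was at least 1.54-fold higher (means 6.53 and 7.67, adjusted p = 0.00233). The immediate early list did not pass without primary 2 (0.0741), primary 3 (0.147), metastatic 1 (0.0624) or metastatic 4 (0.0602, median 0.11). Of 9 heat shock genes 2 rose (2 over the list alone, median 0.16, adjusted p = 0.0227, but 0.249 with an estimated correlation). These were the small heat shock protein Hspb1 (4.69-fold, adjusted p = 0.00021) and the co-chaperone Bag3 (2.63-fold, adjusted p = 0.0078). The heat shock list did not pass without primary 2 (0.0589) or metastatic 3 (0.101). Its median was 0.02 without metastatic 3, 0.26 without primary 3 and 0.25 without metastatic 1. Granule neuron differentiation genes fell as a list although 0 of 20 passed singly or over the list alone (median -0.63, adjusted p = 0.0053, but 0.483 with an estimated correlation, and 0.0656 without primary 4). Gabrd, a GABA receptor subunit of granule neurons, differed by -1.64 (adjusted p = 0.204).

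SHH signalling, proliferation and progenitor genes did not pass as lists in camera. For the SHH pathway 0 of 14 genes passed (median -0.05, adjusted p = 0.695). Ptch1, the receptor and a target of the pathway, differed by -0.35 (SE 0.30, 10.69 ± 0.69 against 11.03 ± 0.40, adjusted p = 0.599) and the transcription factor Gli2 by -0.13 (SE 0.25, adjusted p = 0.841). For the cell cycle 0 of 29 passed (median 0.02, adjusted p = 0.811), with the proliferation marker Mki67 at 13.09 ± 0.27 against 12.86 ± 0.25 (adjusted p = 0.627). For granule progenitor factors 0 of 9 passed (1 lower over the list alone, median -0.27, adjusted p = 0.103, but 0.0327 with fry). The mean of that list differed by -0.32 and was lower in all 4 pairs of replicate numbers (-0.57 to -0.18, exact two-sided permutation p = 0.125 by sign flips within pairs, the smallest possible, and 0.0286 without pairs).

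The other pathway lists did not pass either, with single members that did. In the Notch pathway (1 of 15, and 3 higher and 1 lower over the list alone, median 0.16, adjusted p = 0.137) Heyl rose at least 1.73-fold (means 6.70 and 7.84, adjusted p = 0.00207). In the Wnt pathway (1 of 12, and 3 higher and 3 lower over the list alone, median -0.09, adjusted p = 0.835) Nkd2 rose 2.28-fold (adjusted p = 0.00414). Among p53 targets (1 of 16, and 1 over the list alone, median -0.01, adjusted p = 0.637) Phlda3 rose 2.85-fold (adjusted p = 0.000331). For neuronal migration and guidance 4 of 22 rose (4 higher and 1 lower over the list alone, median -0.29, adjusted p = 0.835). Among them was the semaphorin receptor Nrp1 at 3.16-fold (adjusted p = 0.0107). The other rises were less firm. Cxcl12 had 2 further probes that fell (-0.51 and -0.45) and did not pass with the mean of its probes (0.25, adjusted p = 0.755). Slit2 passed with that mean (0.90, 0.0454), but its other probe differed by 0.01. Efnb1 (0.0338) did not pass with a replicate block (0.0543). For hypoxia and glycolysis 1 of 15 rose (1 over the list alone, median 0.02, adjusted p = 0.212), Ndrg1 at 5.27-fold (adjusted p = 5.97e-05). No ribosomal protein gene passed among 15 (median -0.05, adjusted p = 0.154), nor any of 5 sex-linked genes (median -0.13, adjusted p = 0.991).

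Of the remaining cell type lists, oligodendrocyte markers did not pass (2 higher and 1 lower over the list alone, median 0.79, adjusted p = 0.103). Among 13 members Mal, a myelin protein, rose from a mean of 6.68 to 9.30 (adjusted p = 0.000144) and Olig1, a lineage transcription factor, fell by 1.24 (adjusted p = 0.0174, and up to 0.065 without primary 2 or metastatic 2 or 3). Mbp, at 14.09 ± 0.99 against 10.74 ± 1.68, did not pass (adjusted p = 0.0808, but 0.0265 without primary 1, and 0.0234 with a replicate block and only these 8 arrays). Astrocyte markers (1 of 13 lower, 1 higher and 1 lower over the list alone, median -0.29, adjusted p = 0.605) and Purkinje cell and interneuron markers (1 of 7 lower, 1 higher and 2 lower over the list alone, median -0.22, adjusted p = 0.352) did not pass. Choroid plexus and ependymal markers rose in 2 of 7 (2 over the list alone, median -0.01, adjusted p = 0.0686): Sostdc1, at least 5.68-fold (means 6.55 and 9.55, adjusted p = 1.68e-05), and the water channel Aqp1, 8.14-fold (adjusted p = 0.00405). Erythroid genes rose in 1 of 3 (1 over the list alone, median 1.09, adjusted p = 0.0686).

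**Figure D2:**
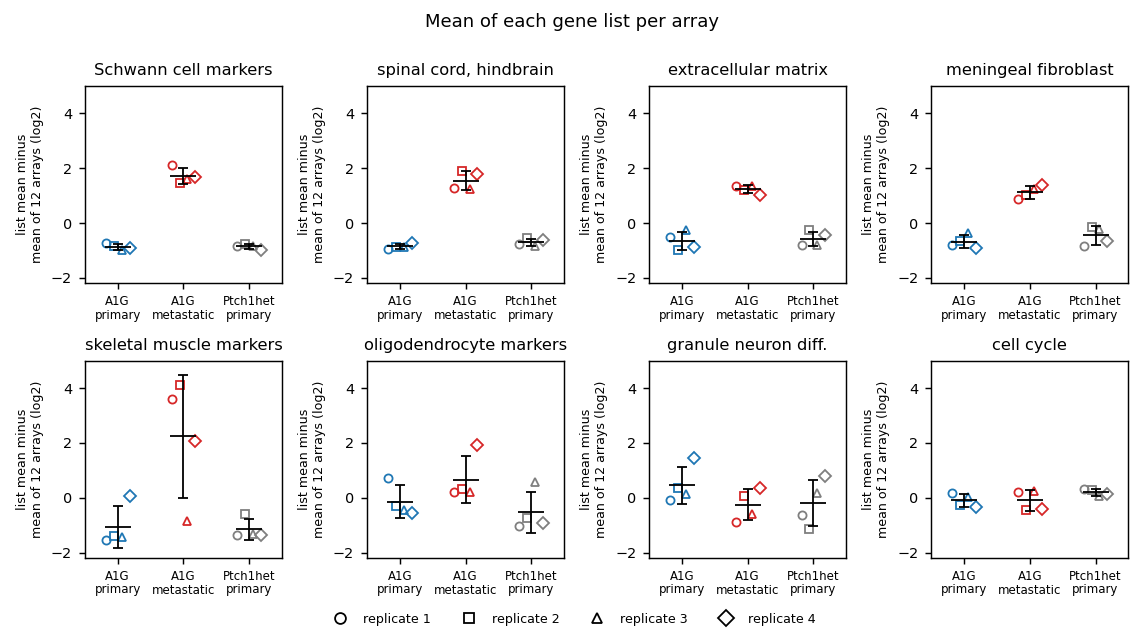
Mean log2 signal of 8 gene lists in each array, minus the mean of all 12 arrays, by group, with bars for mean ± SD (n = 4). Schwann cell markers averaged 10.21 in metastatic and 7.62 in A1G primary tumours before the subtraction.

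In all, 873 of 16724 genes passed (5.22%), 749 higher and 124 lower in metastatic than in A1G primary tumours, and 183 rose and 9 fell at least 4-fold. The groups did not overlap in 2172 genes, 13% against 2.86% by chance. Of the 30 lists 14 rose and 1 fell, but 4 passed with an estimated correlation. The count of genes was 428 with probes required above the median on all 12 arrays, 425 with only metastatic replicates 1 and 4, and 1462 with a replicate block and only these 8 arrays.

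Between the primary tumours of the 2 genotypes, 6 of 16724 genes passed (0.0359%). The eGFP probe, which reads a reporter absent from the mouse genome, was higher in A1G primary than in Ptch1het tumours by 4.70 on the log2 scale (SE 0.42, 12.28 ± 0.61 against 7.58 ± 0.40, n = 4, adjusted p = 0.000892), a lower bound if the Ptch1het reading is background. Pou4f1, a transcription factor of sensory and some central neurons (chromosome 14), differed by -3.58 (SE 0.36, 7.17 ± 0.84 against 10.75 ± 0.41, adjusted p = 0.0011). Hrk, a pro-apoptotic BH3-only gene (chromosome 5), was lower by at least 3.13-fold (means 6.71 and 8.69, adjusted p = 0.00102), and Tbx4, a T-box transcription factor, differed by -1.62 (SE 0.16, 7.13 ± 0.08 against 8.75 ± 0.27, adjusted p = 0.0011).

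The other genes passed less firmly. Tmem229a differed by -1.58 (SE 0.22, 7.31 ± 0.19 against 8.90 ± 0.43, adjusted p = 0.0257, and up to 0.126 without any one A1G primary or without Ptch1het 1, 2 or 3, and 0.0785 with the mean of its probes). Nat2, an arylamine acetyltransferase, differed by -1.24 (SE 0.16, 7.38 ± 0.09 against 8.62 ± 0.24, adjusted p = 0.0118, and up to 0.067 without A1G primary 2 or 3 or Ptch1het 3). Among the smallest p-values that did not pass, the lowest differences were Gpat2 at -2.58 (adjusted p = 0.0667, and down to 0.0196 without Ptch1het 2 or 4) and Adcyap1 at -1.61 (adjusted p = 0.0801, and down to 0.0221 without Ptch1het 1 or 4). The highest were Ank1 at 2.14 (adjusted p = 0.0863) and LOC100046690 at 2.03 (adjusted p = 0.108), which passed without Ptch1het 4 (0.0452 and 0.0483).

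**Figure D3:**
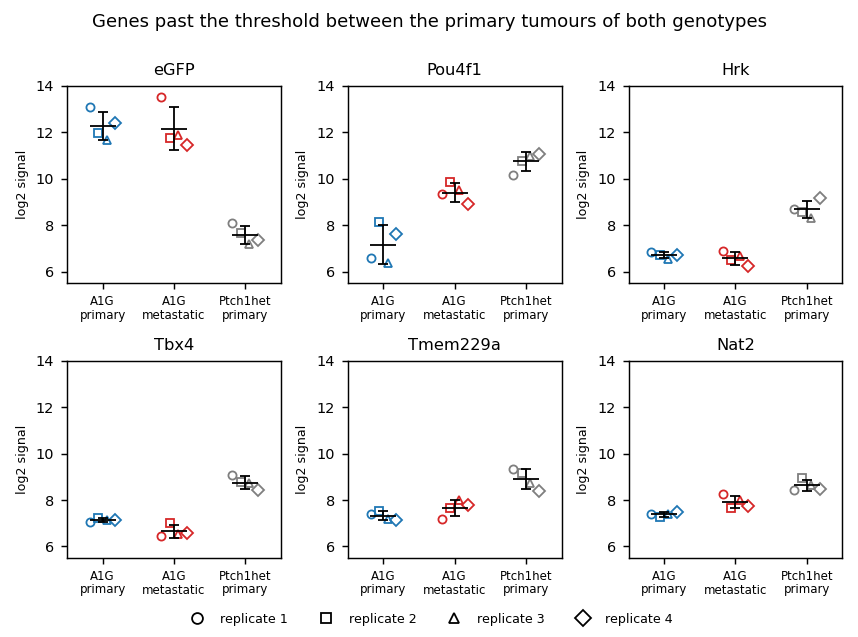
Log2 signal of the 6 genes that passed between A1G primary and Ptch1het tumours, in each array of the 3 groups, with bars for mean ± SD (n = 4). The eGFP probe averaged 12.28 in A1G primary and 7.58 in Ptch1het tumours.

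Neuronal and cell cycle lists differed between the genotypes at the preset correlation, without a passing member. Granule neuron differentiation genes were higher in A1G primary tumours (0 of 20, 1 over the list alone, median 0.69, adjusted p = 0.000553, but 0.994 with an estimated correlation, and 0.0756 without Ptch1het 2, with a median of 0.36). Their mean per array ran from 10.92 to 12.44 in A1G primary and from 9.87 to 11.80 in Ptch1het tumours, highest in replicate 4 of both. Nfia, a transcription factor of granule neuron maturation, differed by 0.76 (adjusted p = 0.167). Cell cycle genes were lower (0 of 29, 1 over the list alone, median -0.22, adjusted p = 0.00259, but 0.994 with an estimated correlation, and 0.0726 without A1G primary 4). The cyclin Ccna2 differed by -0.97 (adjusted p = 0.123). The SHH pathway list did not pass (median 0.05, adjusted p = 0.986). Ptch1 differed by -0.16 (11.03 ± 0.40 against 11.19 ± 0.15, adjusted p = 0.849), Gli2 by 0.27 (adjusted p = 0.672) and the target Hhip by -0.98 (adjusted p = 0.0946).

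The other 27 lists did not pass, among them extracellular matrix (median -0.01, adjusted p = 0.986) and sex-linked genes (median -0.82, adjusted p = 0.894). The Y-linked Eif2s3y read above 10 in 1 of 4 A1G primary and 3 of 4 Ptch1het tumours, so the sexes were unevenly spread between these groups. An unadjusted p under 0.05 was reached by 2238 genes against 836 by chance, and 1127 genes did not overlap (6.74% against 2.86% by chance). The count of 6 depended on single libraries: it was 60 without Ptch1het 4 (38 higher, 22 lower) and 10 without Ptch1het 2. It was 3 with probes required above the median on all 12 arrays.

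In the secondary comparison of A1G metastatic with Ptch1het tumours, genotype and site differed together. Genes of peripheral neurons were among the largest rises. Scn11a rose by a log2 difference of 5.22 (means 6.59 and 11.81, adjusted p = 0.000165), Sncg 36.5-fold (8.35 ± 1.34 to 13.54 ± 0.47, adjusted p = 4.71e-05) and Prph at least 39.6-fold (means 6.76 and 12.35, adjusted p = 8.75e-08). The eGFP probe was higher by 4.58 on the log2 scale (adjusted p = 2.36e-05), again a lower bound if the Ptch1het reading is background. Hrk was at least 3.13-fold (means 6.57 and 8.69, adjusted p = 2.08e-05) and Tbx4 at least 3.25-fold (6.64 and 8.75, adjusted p = 6.09e-06) lower. Krt12, a keratin, differed by -2.46 (SE 0.47, 9.21 ± 0.54 against 11.67 ± 1.04, adjusted p = 0.0065) and Lmo3, a LIM-only transcriptional cofactor, by -2.14 (SE 0.32, 7.29 ± 0.65 against 9.43 ± 0.29, adjusted p = 0.00123). The SHH target Hhip differed by -1.22 (adjusted p = 0.00132), while the co-receptor Cdon differed by 1.22 (adjusted p = 0.0129) and Ptch1 did not pass (-0.51, adjusted p = 0.284). The SHH pathway list did not pass (2 higher and 1 lower of 14, 2 and 1 over the list alone, median -0.12, adjusted p = 0.822).

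In metastatic against Ptch1het tumours 4 lists passed under both correlations (each adjusted p = 0.00989 with an estimated correlation). Extracellular matrix genes rose in 20 of 26 (23 over the list alone, median 1.71, adjusted p = 8.97e-23). Col1a1 rose 11.3-fold (adjusted p = 6.07e-05) and the laminin chain Lama2 3.01-fold (adjusted p = 3.76e-05). Spinal cord and hindbrain genes rose in 12 of 16 (12 over the list alone, median 2.44, adjusted p = 1.74e-15), with Hoxc6 at least 14.5-fold higher (means 6.11 and 10.91, adjusted p = 3.47e-08). Schwann cell markers rose in 6 of 8 (7 over the list alone, median 2.85, adjusted p = 2.5e-14). Meningeal fibroblast markers held 8 rises and 1 fall among 18 (14 and 1 over the list alone, median 1.65, adjusted p = 1.08e-09), with the transporter Slc13a4 higher by 2.34 on the log2 scale (adjusted p = 0.00129).

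Further lists passed at the preset correlation only, with adjusted p from 0.16 to 0.713 when the correlation was estimated. Skeletal muscle markers rose in 6 of 7 (7 over the list alone, median 3.87, adjusted p = 8.47e-06) and interferon and MHC genes in 7 of 25 (14, and 1 lower, over the list alone, median 0.94, adjusted p = 2.78e-08). The MHC class I gene H2-D1 rose 3.01-fold (adjusted p = 0.000828), although 1 of its 2 other probes differed by -0.28 and the mean of its probes by 0.94, and Cd74 5.63-fold (adjusted p = 0.00453). Microglia and macrophage (4 of 20, 6 over the list alone, adjusted p = 4.73e-06), epithelial-mesenchymal transition (5, 7 so adjusted, of 22, 1.45e-05) and lymphocyte genes (4, 5 so adjusted, of 9, 0.00109) also rose. So did mural cell (3, 4 so adjusted, of 10, adjusted p = 0.00245), BMP and TGF-beta (3, 6 so adjusted, of 13, 0.00401) and immediate early genes (2, 2 so adjusted, of 15, 0.0228). The remaining calls depended on single libraries. They were oligodendrocyte markers (3 of 13 higher, adjusted p = 0.00859, 0.0541 without metastatic 4), choroid plexus and ependymal markers (2 of 7, 0.0304, 0.084 without Ptch1het 4, where the median turned from 0.43 to -0.13) and endothelial markers (2 of 16, 0.0438, and up to 0.31 without metastatic 2 or 4 or Ptch1het 3). Erythroid genes were a further such list (1 of 3, 0.0456, and up to 0.111 without metastatic 2 or 4 or Ptch1het 2, 3 or 4), as were cell cycle genes (2 of 29 lower, median -0.18, 0.0275, and up to 0.212 without metastatic 2 or 4 or Ptch1het 2). The cell cycle median was -0.11 without metastatic 2 and -0.42 without Ptch1het 3.

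In this comparison 1647 genes passed (9.85%), 1032 higher and 615 lower, and 2618 did not overlap (15.7% against 2.86% by chance). The count was 791 without metastatic 2, 1007 without metastatic 4, 1042 with only these 8 arrays, 601 with only metastatic replicates 1 and 4, and 734 with only metastatic replicates 2 and 3.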

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

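Single arrays were picked out by a criterion fixed beforehand, Dixon's test at the 95% level. It weighs the gap between an array and the nearest of its group. Of the genes named in the text 130 were tested, of which some were named after their values were seen. The criterion was met by 26 of 390 gene and group combinations (6.67%), where chance alone gives about 19.5. The values below are log2 signal and no cause was tested for any of them.

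In A1G primary tumours, replicate 4 was above the others for Tnnc2 (14.10 against 6.22 to 6.42), Gabrd (11.12 against 7.93 to 8.37), Scn11a (8.42 against 5.91 to 6.29) and Hoxa9 (6.67 against 6.09 to 6.18). Replicate 1 was below the others for Mfap5 (5.84 against 6.39 to 6.46), Atp2a1 (6.88 against 7.03 to 7.05), Mrc1 (7.86 against 8.43 to 8.52), Zic1 (13.77 against 14.23 to 14.27) and Slc13a4 (6.72 against 7.21). Replicate 3 was above the others for Bgn (11.98 against 11.06 to 11.15) and Hoxc8 (7.56 against 7.24 to 7.25) and below them for Cspg4 (8.45 against 8.94 to 8.95). Replicate 2 was above the others for Eif2s3y (10.62 against 6.12 to 6.29).

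In metastatic tumours, replicate 2 was above the others for Tmem45b (12.40 against 10.30 to 10.51) and Eif2s3y (10.68 against 5.93 to 6.12). Replicate 4 was above them for Sox10 (12.34 against 11.32 to 11.43) and Lama2 (8.97 against 8.58 to 8.61) and below them for Sostdc1 (8.60 against 9.82 to 9.97) and Hoxc8 (7.01 against 7.28 to 7.32). Replicate 3 was above them for Cbln1 (13.73 against 13.09 to 13.19).

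In Ptch1het tumours, replicate 1 was below the others for Bgn (10 against 11.43 to 11.60) and above them for Adcyap1 (10 against 8.55 to 8.71) and Pcna (10.01 against 9.43 to 9.50). Replicate 2 was below the others for Zic1 (13.76 against 14.15 to 14.23) and Hoxb5 (6.19 against 6.67 to 6.75), and replicate 4 was below them for Eif2s3y (5.84 against 10.62 to 11.09).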

How the results depend on the processing

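Among the genes chosen by the naming rule and the lists that passed, none changed direction past the threshold in the alternatives where direction was followed. For lists this was the direction given by camera. With every probe on its own only counts were followed. Among passing genes of the naming rule with several probes, 1 of 32 had an opposite probe in metastatic against A1G primary tumours. In metastatic against Ptch1het tumours it was 6 of 37. With other background corrections, the deposited values as they are, or median centring, 861 to 873 genes passed between metastatic and A1G primary tumours and 6 between the genotypes. Under the alternatives below the counts moved by more than 1.5 times; the cause was not tested except where fewer probes, arrays or a stricter threshold shows it. For genes in metastatic against A1G primary tumours the count, 873, was 428 with a filter on all 12 arrays, 1339 with array weights, 463 at an adjusted p under 0.01, 425 with only metastatic replicates 1 and 4, and 1462 with a replicate block and 8 arrays. For genes in A1G primary against Ptch1het tumours the count, 6, was 3 with the filter on all 12 arrays and 14 with both replicates 4 left out. For genes in metastatic against Ptch1het tumours the count, 1647, was 1042 with only 8 arrays, 570 at an adjusted p under 0.01, 601 with metastatic replicates 1 and 4 and 734 with replicates 2 and 3. The filter on all 12 arrays, the block with 8 arrays and the choices of replicates were added after the data were seen.

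For lists, an estimated correlation left 4 of 15, 0 of 2 and 4 of 17 calls in the 3 comparisons in the order given, and fry gave 11, 0 and 10. In metastatic against A1G primary tumours, fry also passed epithelial-mesenchymal transition and lymphocyte genes (each adjusted p = 0.00185) and BMP and TGF-beta genes (0.00858). Skeletal muscle (0.0211) and heat shock genes (0.0265) passed fry as well. So did choroid plexus and ependymal markers (0.00509) and granule progenitor factors (0.0327), which had not passed in camera. The filter on all 12 arrays left 10 lists between metastatic and Ptch1het tumours, with fewer members tested, and leaving out both replicates 4 left 1 list between the genotypes.

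When each array was left out in turn, between 605 and 865 genes and 13 and 18 lists passed in metastatic against A1G primary tumours, 4 and 60 genes and 1 and 3 lists in A1G primary against Ptch1het tumours, and 791 and 1645 genes and 14 and 18 lists in metastatic against Ptch1het tumours. Of the genes chosen by the naming rule that passed, 50 of 77, 4 of 6 and 52 of 87 kept the call in every such fit.

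With the replicate number as a block on all 12 arrays, 970, 6 and 1895 genes and 16, 2 and 17 lists passed. Among the genes chosen by the naming rule in the paired comparison, the block ended 4 calls, including Ptprz1, and made 4; it changed no other call among them and ended no list call. A1G primary and Ptch1het arrays of the same number correlated at 0.17, -0.01, 0.08 and 0.34, and metastatic and Ptch1het arrays at 0.04, 0.01, -0.07 and 0.08, so these numbers were not taken as pairs; in the first of these comparisons the block moved Tmem229a and Nat2 to an adjusted p of 0.0512.

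Background correction by neqc itself, the filter on detection p and the chip as a block were planned but not run, since the columns they need match no sample. Signal near background limits the folds of dim genes: 157 genes that passed between metastatic and A1G primary tumours were at or below the array median in every array of one group.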

Other observations

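Gene families were examined by symbol after the results were seen. Hox genes, which pattern the body axis, were raised in metastatic against A1G primary tumours mainly in the middle paralog groups: 3 of 8 genes of groups 2 to 5 (Hoxd4, Hoxa5 and Hoxb5) rose, 8 of 9 of groups 6 to 9, and 0 of 4 of groups 10 to 13. The exception among groups 6 to 9 was Hoxc8 (-0.10, adjusted p = 0.794). Outside the fixed list, Hoxc9 (means 9.61 and 6.13, adjusted p = 3.2e-08), Hoxd9 (7.80 and 6.53, adjusted p = 0.01) and Hoxa9 (7.32 and 6.28, adjusted p = 0.004) rose, and the 10 such genes passed together (p = 0.00885 with an estimated correlation in camera). Against Ptch1het tumours these 10 genes did not pass together (2 higher, median 0.12, p = 0.0575 with an estimated correlation).

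Collagen genes rose in 17 of 35 members (median 1.25, camera p = 0.00145 with an estimated correlation), and in 7 of 25 outside the fixed lists (median 0.65, p = 0.00162). Keratin genes, taken as a contrast, rose in 1 of 13 (median -0.09, camera p = 0.847 with an estimated correlation). A later list of adipocyte genes had a median of 1.18 with 0 of 6 passing (camera p = 0.00999, but 0.245 with an estimated correlation); its most abundant member, Lpl, averaged 12.74 in metastatic and 11.73 in A1G primary tumours.

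The first pattern weighed, with tests chosen after the result was seen, is the rise of peripheral nerve, trunk Hox and matrix genes in metastatic tumours. As a hypothesis, RNA from tissue next to the metastases, such as spinal roots and their coverings, may contribute: a later list of sensory neuron genes, none also on a fixed list, rose with it (camera p = 0.00194 with an estimated correlation), with 5 of 10 passing: Scn10a, Trpv1, Calcb, Htr3a and Gal. Its most abundant members, Uchl1 (12.49 against 11.55) and Ret (10.85 against 9.52), did not pass. Whether a lower share of tumour cells alone could give the rise was not decided. Markers of other cell types did not rise alike. The Schwann cell list rose more than the astrocyte list by 2.85, beyond its SDs of 0.96 and 0.36. In the 4 pairs of replicate numbers this was 1.74 to 3.72. The exact two-sided permutation p was 0.125 by sign flips within pairs, the smallest possible, and 0.0286 without pairs. The Schwann cell list was already known to rise when this contrast was chosen. Tissue next to the metastases that takes the place of tumour cells could also raise it alone. Expression by the tumour cells themselves stays open. The eGFP level differed by -0.13 (SE 0.42, 95% interval -1.03 to 0.77). Such a level cannot decide the question, since it does not show which cells carried the rises.

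The second, with tests also chosen afterwards, is the lower level of Gpr17, Cspg5 and Nkx2-2 in metastatic than in A1G primary tumours. A later list of oligodendrocyte progenitor genes was lower (median -0.63, camera p = 0.0141 with an estimated correlation), as fewer such cells in the sampled tissue could give. Of its genes 4 were also on fixed lists, among them Pdgfra (meningeal fibroblast), Cspg4 (mural cell) and Sox10 (oligodendrocyte). The meningeal list rose, so the level of Pdgfra does not follow progenitors alone. The mural cell list rose at the preset correlation, and the oligodendrocyte list had a median of 0.79. The levels of Cspg4 and Sox10 may therefore not follow progenitors alone either. Among the 11 genes of the progenitor list Neu4 and Cspg4 passed. Its most abundant members, Pdgfra (12.06 against 12.47) and Sox10 (11.63 against 11.68), did not. That list was also higher in A1G primary than in Ptch1het tumours (median 0.31, p = 0.0414 with an estimated correlation) and did not pass between metastatic and Ptch1het tumours (median -0.27, p = 0.3 with an estimated correlation), so for the list a high level in A1G primary tumours stays as open as a fall, whereas Cspg5 was lower than in Ptch1het tumours too (-2.13, adjusted p = 0.00505, and -1.26 with the mean of its probes). Dilution of the tumour by other tissue alone was weighed by taking eGFP and granule progenitor factors as carried by the tumour cells. Gpr17 and Cspg5 fell further than these. Minus the mean of those factors they differed by -2.81 and -2.19, and minus eGFP by -3.00 and -2.38. The 95% intervals, unadjusted and without pairs, all ended at or below -0.18. Both genes were picked as large falls and parted from Nkx2-2 after the intervals were seen, so dilution was not excluded for them. It also stays open for Nkx2-2, whose interval minus eGFP reached 0.26, and for the progenitor list. The difference of that list from the granule progenitor list shifted by -0.27, and by -0.36 to -0.19 in the 4 pairs. The exact two-sided permutation p was 0.125 by sign flips within pairs, the smallest possible, and 0.257 without pairs.

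The third, with tests again chosen afterwards, is the lower level of Pou4f1, Hrk, Tbx4, Tmem229a and Nat2 in A1G primary than in Ptch1het tumours. With Eif2s3y as a covariate 4 of the 5 genes still passed. These were Hrk, Tbx4 and Pou4f1 (adjusted p = 0.00252, 0.00252 and 0.00863) and, just under the threshold, Nat2 (0.0496). Tmem229a did not pass (-1.41, adjusted p = 0.119). The covariate rests on Ptch1het 4, the only Ptch1het array low in Eif2s3y (5.84). Its Xist signal was 8.17, against 11.75 to 13.04 in A1G primary 1, 3 and 4, so its sex is unsure. The uneven spread of the sexes was therefore not excluded for any of the 5 genes. A strain variant under the probe may account for single genes and stays open. Only 1 of the 5 genes, Tmem229a, had a further probe in the same direction, at -0.11. The chip could not be tested.

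Whether chance can be excluded was tested by regrouping the 8 arrays of each comparison in all 35 ways into 4 and 4, a test planned beforehand. For genes, as many calls came in 1 of 35 splits, the real one, in each comparison. Chance was thereby excluded only if replicate numbers are not pairs. In metastatic against A1G primary tumours there were 873 real calls against a highest other count of 1. Among the 8 splits that part all pairs the highest other count was 0. With pairs the share cannot fall below 1 of 8, so chance cannot be excluded in that way. Between the genotypes there were 6 calls against 2, with the eGFP reporter among the 6. That margin rests on few genes. The count was 3 with the filter on all 12 arrays, 4 without A1G primary 2 or 3 or Ptch1het 3, and 60 without Ptch1het 4. In metastatic against Ptch1het tumours there were 1647 calls against 2. For lists at the preset correlation, chance could not be excluded in 2 comparisons: 5 splits gave at least the 15 real calls in metastatic against A1G primary tumours (highest other 19, or 14 among the 8 splits that part all pairs), and 32 gave at least the 2 real calls between the genotypes (highest other 11). In metastatic against Ptch1het tumours it was excluded by a margin of 1 list (1 split, 17 real against 16), less than the count moved under other choices (16 without background correction, 14 to 18 with 1 array left out). With an estimated correlation, a count added afterwards, the 4 real list calls in metastatic against A1G primary tumours stood against a highest other of 2.

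The Y-linked Eif2s3y was high in replicate 2 alone of both A1G primary and metastatic tumours (10.62 and 10.68), and Xist was low in the same 2 arrays (6.40 and 5.98).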
